A study of Caenorhabditis elegans with 2 samples.

How the data were processed

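UNC-62 ChIP-seq peak lists from whole L4 larvae were analysed for 1 group of 2 biological replicates, each with 1 technical replicate per the labels. The labels name UNC-62 as the antibody's target and describe a line stably expressing UNC-62 with a C-terminal GFP-FLAG tag; chromatin was sheared by sonication per the labels. Each deposited list is in narrowPeak format in ce11 and in ce10. Per the deposited readme texts, 1 list was made from each replicate and 1 from both replicates pooled, each against a control alignment from another series, which was not analysed here, and the optimal IDR list was made from these by IDR thresholding. The aligner, the peak caller and the IDR threshold are not given in the sources used here.

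The authors' signal value of each peak, from the deposited lists, was used mainly to rank peaks within a list. Its size entered only Pearson's r, the comparison of weak peaks around unc-62 and the description of single peaks. The deposited q-value column was treated as a score, because it falls below 0 at 29433 of the 30000 pooled peaks, and it was not used in any test. Peaks were of fixed width, 376 bp in the ce11 IDR, pooled and replicate 1 lists and 390 bp in that of replicate 2. The pooled list has exactly 30000 peaks in both builds and includes weak background regions, so membership in it is not evidence of binding. Read counts are not in these lists, and depth is unknown. Intervals on shares are 95% exact Clopper-Pearson intervals, which cover counting error over peaks only. Where no member of a gene list carried a peak, the upper limit was 3 counts of the total.

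Summits were annotated with the Ensembl release 115 genes of WBcel235, whose coordinates are those of ce11, and no ce11 peak extended beyond a reference chromosome. The ce10 lists were used for counts, overlaps and signals only, since no ce10 annotation was used and no position was converted. Promoters ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, and remaining summits were assigned in turn to exons, introns, non-coding genes and intergenic sequence. IDR summits were compared with the 29857 pooled peaks that overlapped no IDR peak. Sequence windows reached 100 bp to either side of the summit, and each IDR window was compared with 10 background windows matched on promoter status and on GC content in bins of 2.5%. All 1140 background windows could be matched, with neighbouring GC bins used where a bin ran short. Their mean GC content was 45.6%, against 45.7% for the IDR windows. A gene was testable for the list comparison if a pooled summit lay from 2000 bp upstream to 500 bp downstream of a start. Each of the 20 lists and 10 sequences was fixed before the data were examined.

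Shares were compared by Fisher's exact test, two-sided, with conditional odds ratios, and p-values were adjusted by Benjamini-Hochberg over the sequences, the lists, the 5 annotation classes or the 4 site tests. Replicate overlap was tested against 1000 circular shifts along each chromosome, and the correlation across sites with 100000 permutations (1000 for the pooled peaks). Equality of the Meis core odds ratios in promoters and elsewhere was tested exactly, given all margins. Genes were named by a fixed rule. It took the nearest protein-coding gene of the 25 IDR peaks of highest signal, list members with an IDR summit in their window (the 4 of highest signal where a list had more than 5), and unc-62 and unc-119 whatever their values. Alternatives covered the build, a stricter list of 57 peaks at or above the median signal, each replicate's list alone, overlap rules, windows and backgrounds. There was 1 group, so no comparison between conditions was made.

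The tests of promoters, X, tRNA genes, the Meis core, gene lists and replicate overlap were tried on simulated data, and the remaining tests were not. With 114 random background peaks in place of the IDR peaks, 100 draws of the exact test passed p = 0.05 in 2 cases for promoters, 4 for X, 2 for tRNA genes and 3 for the Meis core, and 3 draws gave a list past the adjusted threshold. Random draws lack the clustering and the high GC content of the IDR peaks, so these rates need not hold for peaks like those. TGACAG was planted in windows of 114 random background peaks and counted as recovered at unadjusted p below 0.05 in the exact test. Planted in 10% of the windows it was recovered in 78 of 100 draws, and in 20% of them in 100. Recovery at the adjusted threshold, or in windows as rich in GC as those of IDR peaks, was not simulated. With 4 of 114 peaks placed at ribosomal protein gene starts, the list was recovered in 100 of 100 draws, and with 2 in 8. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.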

Results

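Binding of UNC-62 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae of Caenorhabditis elegans, the last larval stage before adulthood. UNC-62 is a homeodomain protein of the Meis/Homothorax family, whose members act with PBC and Hox proteins in development. The labels describe 1 group with 2 biological replicates from strain OP602, a stable transgenic line of mixed sex in which UNC-62 carries a C-terminal GFP-FLAG tag, and speak of an insertion that targets unc-62. The data are peak lists in 2 genome builds. In ce11 the list of replicate 1 held 15466 peaks, that of replicate 2 held 24524, the list from pooled replicates held 30000, and the list thresholded by the irreproducible discovery rate (IDR) held 114. In ce10 these lists held 25171, 23275, 30000 and 140 peaks, so the order of the replicates differs between the builds, for a reason the files do not give. Read depth is unknown, so the number of peaks sets the precision of each share below. All coordinates are in WBcel235 (ce11) and count from 1.

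In the ce11 IDR and pooled lists, UNC-62 ChIP signal was strongest in the unc-62 gene itself. The peak with the highest signal value of all 114 IDR peaks, 105, lay on chromosome V from 4508030 to 4508405, with its summit at 4508218. This position is in an exon annotated as 5' UTR of an unc-62 transcript, 1014 bp downstream of the nearest annotated start. The strongest peak overlapping it ranked 1 in replicate 1 and 2 in replicate 2, where the peak at rpl-3 ranked 1. In replicate 2 the peak of rank 2 had its summit at 4508039, and that of rank 8, with its summit at 4508263, also overlapped the IDR peak. The ce10 lists, which were not annotated, had a mitochondrial peak at rank 1 of the IDR and pooled lists. The peak of rank 4 had a signal value of 72.1 and its summit at 4499640, in a 5' UTR 152 bp downstream of another unc-62 start. Its window held the Meis core sequence TGACAG from 4499694 to 4499699. IDR peaks of ranks 61 and 71 also had their summits inside the gene, which spans 4497461 to 4511449 on the plus strand. A further peak of rank 46 lay 7621 bp upstream of the gene, in intergenic sequence. The transcript start nearest to it was that of exc-15, at 6381 bp. In all, 4 of the 11 pooled summits inside unc-62 belonged to IDR peaks. The neuronal gene unc-119, often used as a marker in worm transgenes, carried no IDR peak. Its strongest pooled peak, with the summit on chromosome III at 10905366 inside the gene, had a signal value of 30.6 and pooled rank 145. That site ranked 64 in replicate 1 and 2485 in replicate 2.

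**Figure D1:**
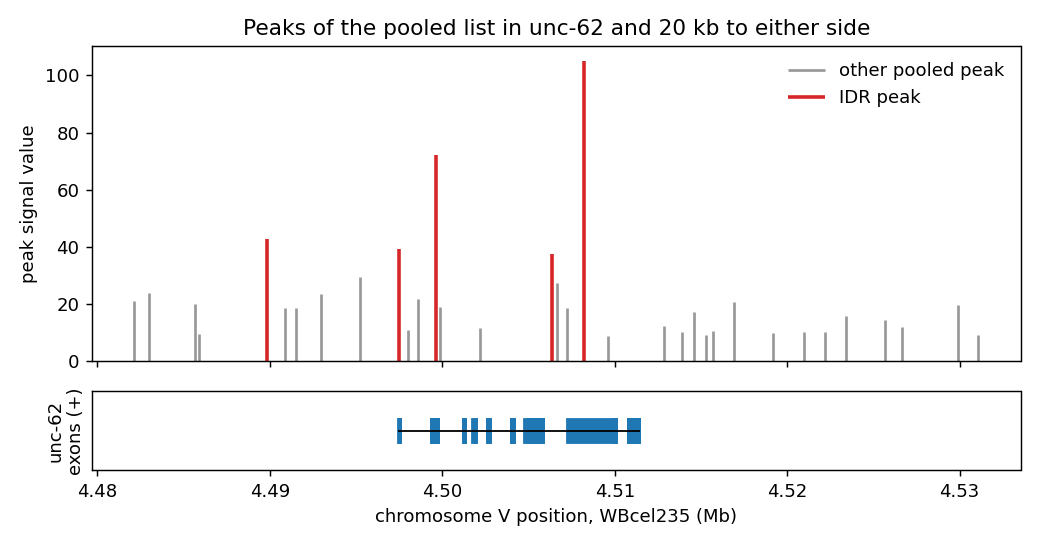
Signal value of each pooled-list peak (y axis) at its summit on chromosome V (x axis, Mb), in unc-62 and 20000 bp to either side, with the exons of all annotated transcripts drawn below. The 5 IDR peaks are in red and include the peaks of signal value 105 and 72.1, and the other pooled peaks are in grey.

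The remaining peaks among the 25 with the highest signal lay at genes of varied function. Of the 25 summits, 9 were in promoters, 8 in intergenic sequence, 5 in introns and 3 in exons. Rank 2 had a signal value of 94.4 and lay in an intron of Y111B2A.12 on chromosome III, from 12612470 to 12612845. Rank 3 had a signal value of 89.3 and lay 274 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, on chromosome III from 3867392 to 3867767. Besides rank 4 in unc-62, the other promoter peaks were nearest to nspc-17 (rank 9), egg-5 (rank 10), tasp-1 (rank 12), sor-1 (rank 20), sec-61.G (rank 23), ndk-1 (rank 24) and Y22D7AL.10 (rank 25). Of these genes, egg-5 encodes a pseudophosphatase of the egg-to-embryo transition, and sec-61.G a subunit of the protein translocon. Intergenic summits were nearest to F19H6.5 (rank 5), C33D9.3 (rank 6), ins-13 (rank 7), F55G7.5 (rank 8), fbxb-58 (rank 14), ZK899.6 (rank 15), aakg-1 (rank 17) and xol-1 (rank 18). The gene ins-13 encodes an insulin-like peptide, aakg-1 a gamma subunit of the AMP-activated kinase, and xol-1 a switch of sex determination. The summit of xol-1 lay 4952 bp upstream of its start. Intron summits were nearest to cest-16 (rank 11, inside mom-1), F54F2.6 (rank 13, inside zfp-1), Y43F8B.2 (rank 19) and Y41G9A.17 (rank 22). Exon summits were those of unc-62 (rank 1), of T23G4.127 (rank 21, in its 3' UTR) and of C41A3.2 (rank 16), the last in a coding exon of pks-1 and 15250 bp from the assigned start.

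The replicates were compared site by site. Of the 114 strongest peaks of replicate 1, 46 overlapped a peak among the 114 strongest of replicate 2 by at least 1 bp, a share of 40.4% (95% exact interval 31.3 to 49.9%). Circular shifts of the peaks of replicate 2 gave a mean of 0.1 and at most 2 overlaps (permutation test, one-sided, p = 0.001, the smallest that 1000 shifts can give). IDR peaks were the 114 of highest signal in the pooled list. All but 1 overlapped a peak of replicate 1, and all but 1 a peak of replicate 2, against 43.3% and 56.1% of all pooled peaks. Such overlap follows from how IDR peaks were selected and is no separate test of agreement. Of the pooled peaks, 6015 overlapped a peak of both replicates and 6200 a peak of neither. Outside the 1000 strongest peaks of replicate 1 lay 16 IDR peaks, and outside those of replicate 2 lay 4. Replicate 2's top list contained 82 peaks that overlapped an IDR peak, and replicate 1's contained 66. At the 112 IDR peaks with a peak in both lists, the signal values of the replicates had a Spearman rho of 0.12 (permutation test, two-sided, p = 0.212), which did not pass the threshold. Pearson's r, which was added after seeing the data, was 0.371 (permutation test, two-sided, p = 0.00016), and 0.163 (permutation p = 0.0893) without the 2 sites farthest from the median of replicate 1, which were ranks 1 and 2. This correlation is across sites, which are not independent replicates, and the sites were selected on the signal of both replicates together. Over all 6015 pooled peaks with a peak in both lists, a set chosen after seeing the data, rho was 0.17 (permutation p = 0.001).

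**Figure D2:**
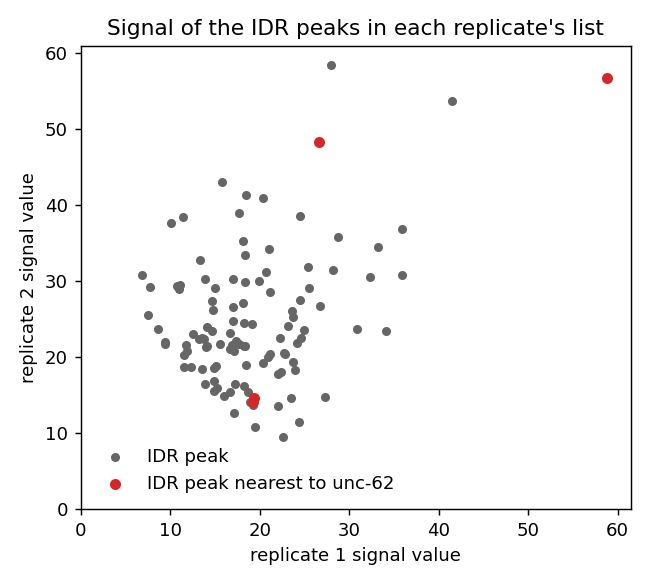
Signal value in the list of replicate 1 (x axis) against that of replicate 2 (y axis) for the 112 IDR peaks with a peak in both lists, each point being 1 peak. Peaks nearest to unc-62 are in red, the one at the top right being rank 1, and over all 112 points Spearman's rho was 0.12 and Pearson's r 0.371.

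IDR summits lay in promoters of protein-coding genes more often, and in exons less often, than the other pooled peaks. A promoter, from 1000 bp upstream to 200 bp downstream of a transcript start, held 51 of 114 IDR summits, or 44.7% (95% exact interval 35.4 to 54.3%), against 29.9% of 29857 other peaks. The odds ratio was 1.90 (95% interval 1.28 to 2.79, Fisher's exact test, two-sided, p = 0.000951, adjusted p = 0.0038 over the 4 fixed site tests of promoters, X, tRNA genes and the Meis core). Exons outside promoters held 6 IDR summits, or 5.26%, against 23.6% (odds ratio 0.18, Fisher's exact test, adjusted p = 1.02e-06 over 5 classes). Introns held 20.2% against 23.7% and intergenic sequence 28.1% against 20.1%, and neither difference passed the adjusted threshold (Fisher's exact test, adjusted p = 0.55 and 0.0763). The promoter call of the exact test was lost in the stricter list of 57 peaks (odds ratio 1.37, p = 0.25), with replicate 1's peaks alone (1.48, p = 0.0506) and with a window of 2000 bp upstream and 500 bp downstream (1.43, p = 0.0609). Such p-values compare sites in these libraries, and neighbouring sites are not independent.

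**Figure D3:**
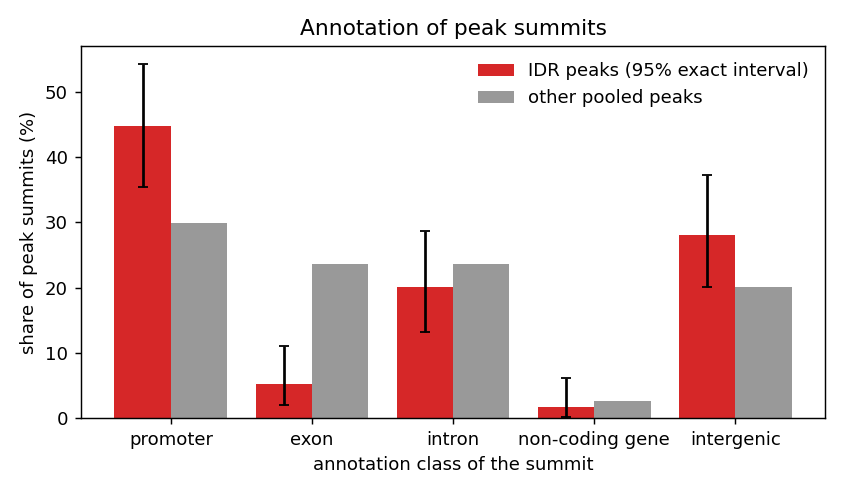
Share of peak summits (y axis, percent) in each annotation class (x axis) for the 114 IDR peaks in red, with 95% exact binomial intervals, and for the 29857 other pooled peaks in grey. Promoters held 44.7% of IDR summits against 29.9%, and exons 5.26% against 23.6%.

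Chromosome X carried 31 of the 114 IDR peaks, or 1.75 per Mb, and chromosome III carried 23, or 1.67 per Mb. Each other chromosome had at most 1.05 per Mb, and only X was tested. The X share was 27.2% (95% exact interval 19.3 to 36.3%) against 19.5% of the other pooled peaks. Its odds ratio of 1.54 had an interval that included 1 (0.987 to 2.36, Fisher's exact test, two-sided, p = 0.0437), and the adjusted p over the 4 fixed site tests was 0.0873. The odds ratio was 2.07 in the stricter list of 57 peaks (95% interval 1.13 to 3.68, Fisher's exact test, p = 0.0118), 1.74 against chromosome lengths (exact binomial test, p = 0.0133), 1.60 with the peaks of replicate 2 alone (Fisher's exact test, p = 0.0325) and 1.05 with those of replicate 1 alone (p = 0.816), with none of these p-values adjusted. The other chromosomes carried 11 (I), 16 (II), 14 (IV) and 19 (V). Genes for tRNA, frequent sites of signal in worm ChIP-seq whatever the factor, lay within 500 bp of 1 IDR summit, or 0.877%, against 0.945% of the other peaks (odds ratio 0.928, 95% interval 0.0232 to 5.32, Fisher's exact test, two-sided, p = 1).

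The Meis core TGACAG was present within 100 bp of 15 of 114 IDR summits, and GAGA repeats were present at many more. The TGACAG share was 13.2% (95% exact interval 7.56 to 20.8%) against 7.81% of 1140 background windows matched on GC content and promoter status. The odds ratio of 1.79 (95% interval 0.925 to 3.26) did not pass the threshold (Fisher's exact test, two-sided, p = 0.0718, adjusted p = 0.173 over 10 sequences). In the stricter list of 57 peaks it was 2.55 (Fisher's exact test, unadjusted p = 0.0308). In a split by promoter status, made after seeing the data, TGACAG was in 9 of 51 promoter windows, or 17.6%, against 6.47% of matched windows (odds ratio 3.09, 95% interval 1.22 to 7.17, Fisher's exact test, p = 0.00891, adjusted p = 0.0178 over 6 tests of 3 sequences in both classes). Outside promoters it was in 6 of 63, or 9.52%, against 8.89% (odds ratio 1.08, 95% interval 0.364 to 2.65, Fisher's exact test, p = 0.818). The difference between these odds ratios did not pass an exact test (p = 0.128). Only 3 of the 10 fixed sequences were split in this way, and the adjustment over 6 tests does not cover that choice. TGACAG occurred beside unc-62 (rank 4), Y111B2A.12 (rank 2), nspc-17 (rank 9) and ndk-1 (rank 24). Its matches lay 4 to 85 bp from their summits, and their placement within the windows was not tested. The closest match lay on the X chromosome from 17419987 to 17419992, beside the summit at 17419986. That summit (rank 43, named after its values were seen) was intergenic, 1482 bp downstream of the start of osm-11. GAGAGA was in 49 IDR windows, or 43.0%, against 22.3% (odds ratio 2.63, 95% interval 1.73 to 3.98, Fisher's exact test, adjusted p = 3.21e-05). The Hox-PBC sequence TGATNNAT was in 18.4% against 10.8% (odds ratio 1.87, adjusted p = 0.0674), and the splice-like TTTCAG in 16 IDR windows against 24.7% of the background (odds ratio 0.497, Fisher's exact test, adjusted p = 0.0536). The composite TGATTGACAG, with up to 1 mismatch, was in 1.75% of both sets. The remaining fixed sequences, TGATTGAC, TGATAA, CACGTG, TTCNNGAA and CCGCCC, also did not pass. Over all 2080 sequences of 6 bases, 34 were more frequent and 5 less frequent in IDR windows after adjustment. They were led in the exact test by ACACAC (odds ratio 3.91, adjusted p = 3.82e-06) and AGAGAC (odds ratio 3.34, adjusted p = 4.33e-05), and TGACAG ranked 299 (adjusted p = 0.497). Background windows were not matched on coding sequence, which held 5.26% of IDR summits against 26.6% of the other pooled peaks. Its part in any of these sequence differences was not tested.

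**Figure D4:**
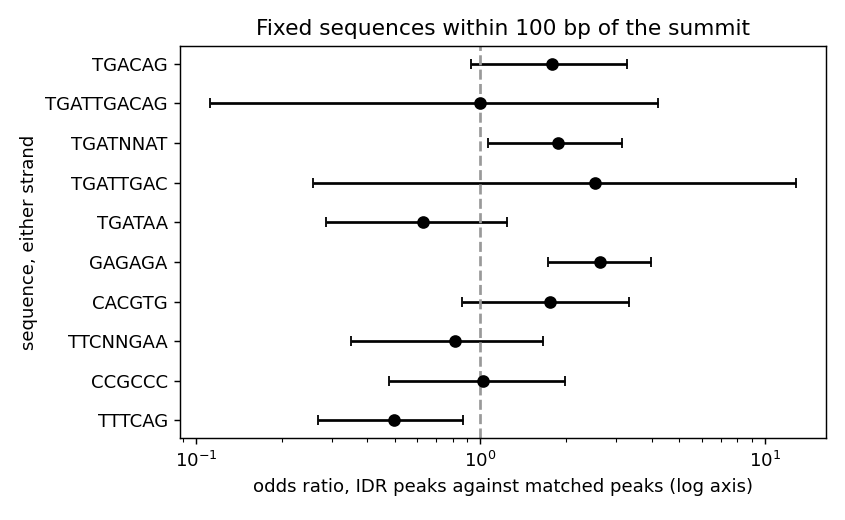
Odds ratio (x axis, log scale) with its 95% exact interval for each of the 10 fixed sequences (y axis) in 114 IDR windows against 1140 matched background windows. GAGAGA lies at 2.63 with its interval above 1, and TGACAG at 1.79 with an interval that includes 1.

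Ribosomal protein genes carried IDR peaks more often than other genes. From 2000 bp upstream to 500 bp downstream of a start, 89 of 12059 testable genes had an IDR summit, or 0.738%. Among ribosomal protein genes these were rpl-3, rpl-15 (rank 72), rpl-22 (rank 76) and rpl-35 (rank 79), that is 4 of 60 testable members (odds ratio 10.005, 95% interval 2.58 to 28.0, Fisher's exact test, two-sided, p = 0.000986, adjusted p = 0.0197 over 20 lists). The summit of rank 76 lay 195 bp upstream of ify-1, its nearest gene, and counted for rpl-22 through the wider window. The call of the exact test was lost with the stricter list (1 member, adjusted p = 1), with replicate 1's peaks alone (2 members, adjusted p = 0.391), with a window of 5000 bp upstream (adjusted p = 0.0919) and when each summit counted for its nearest gene only (3 members, adjusted p = 0.288). Among the 4 testable TALE homeobox genes unc-62 alone had IDR summits (Fisher's exact test, adjusted p = 0.292). The neuropeptide-processing gene egl-3 (rank 78) was the 1 of 13 pan-neuronal genes with an IDR summit (Fisher's exact test, adjusted p = 0.459), and the mitochondrial chaperonin gene hsp-60 (rank 25) the 1 of 9 heat shock and stress genes (adjusted p = 0.43). The summit of rank 25 is the one named above for Y22D7AL.10, its nearest gene, and lay 192 bp upstream of that gene's start. The other 16 lists had no member with an IDR summit in this window, which says little. At the rate of all testable genes their 169 memberships together would hold 1.25 and none of the lists more than 0.192. Outside the window, sma-9 of the mesoblast list was the nearest gene to the summit of rank 82, 3049 bp upstream of its start. This gene was named after its values were seen. The 16 lists were Hox genes, vitellogenins, intestine, fatty acid metabolism, body wall muscle, pharynx, cuticle collagens and cuticle shape, epidermis and seam cell regulators, vulva development, the mesoblast lineage, Wnt signalling and neuroblast migration, germline, sperm, insulin signalling and longevity, heterochronic genes, and histones. Their 2 to 26 testable members each set the precision, since 0 of 16 Wnt genes allows a share of up to 18.8% and 0 of 26 histone genes one of up to 11.5%. The adjusted p of the exact test was 1 for each.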

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

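The ce10 list of replicate 2 held 24 peaks on the mitochondrial chromosome, a signal in lists that the main comparisons did not use and above the 3 counts that a count of 0 allows. The strongest of them had a signal value of 834, against at most 58.5 for any nuclear peak of that list. Replicate 1's ce10 list held 0 such peaks, the pooled list 3 and the ce10 IDR list 2, of which the stronger ranked 1 with a signal value of 358. The ce11 lists of both replicates held 0.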

How the results depend on the processing

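The alternatives without the peaks in or near unc-62, with GC strata, over all pooled peaks, with Pearson's r and by promoter status were chosen after seeing the data. Thresholds are on unadjusted p except for gene lists. The ce10 IDR list held 140 peaks and the stricter list 57, fewer by construction. Replicate overlap was past its threshold under each of 5 alternatives, from 18.5% (top 1000) to 42.1%. The correlation stayed positive, and passed its threshold over all pooled peaks (0.17) and as Pearson's r (0.371; 0.163 without the 2 farthest sites, not passed). The promoter odds ratio stayed above 1 but lost its call in the stricter list (1.37), with the wider window (1.43) and with replicate 2 left out (1.48). It was 1.73 with replicate 1 left out, 1.97 with GC strata and 1.84 without the unc-62 peaks. The X odds ratio ranged from 1.05 to 1.60 when either replicate was left out, and was 1.64 without the unc-62 peaks, 2.07 in the stricter list, 1.74 against chromosome lengths and 1.48 in ce10. The tRNA odds ratio turned above 1 in the stricter list (1.87), against random positions (1.44) and with either replicate left out (1.62 to 3.11), each resting on 1 to 3 peaks. The Meis core passed its threshold in the stricter list (2.55) and in promoter windows alone (3.09), and not outside promoters (1.08). The number of gene lists past the threshold was 0 in the stricter list, with 5000 bp upstream and with nearest genes only, and ranged from 0 to 1 when either replicate was left out. GAGAGA passed its threshold under each of its 7 alternatives, with odds ratios from 2.08 to 6.08. The value of 6.08 was against windows 1000 bp to either side, which were not matched on GC content or promoter status. Against matched windows the highest was 3.51, in the stricter list. The cause of these changes was not tested.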

Other observations

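All tests in this part were chosen after the peak lists were seen; the outcome of the repeat, simple-repeat and flanking-window tests was not known when their criteria were written. With the peaks in or near unc-62 included, IDR peaks lay closer together than random pooled peaks. Within 10000 bp of another IDR summit lay 15 of the 114, in 5 clusters. Random draws from the pooled list, 10000 in all, gave a mean of 2.77 and at most 14 (permutation test, one-sided, p = 1e-04, the smallest these draws can give). Of the 15 peaks, 5 were in or near unc-62, and the test was not repeated without them. Besides the 5 peaks in or near unc-62, 4 lay on chromosome IV between 13694753 and 13704147, around T23G4.127 and the zinc-finger gene tlp-1, with the last 65 bp upstream of tlp-1. Pairs lay at zfp-1, at daf-5, which encodes a Sno/Ski family protein, and at ret-1. IDR windows were also rich in GC, with a mean of 45.7%, and the mean fell with pooled rank to 41.1% at ranks 115 to 500 and 35.7% at ranks 20001 to 30000, against 35.5% at random positions.

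The cluster at unc-62 may reflect binding of the protein at its own gene, which was not tested, or extra copies of the locus in the tagged line. Repeated sequence is argued against as the main cause only as far as masking marks it. Short GA repeats were not tested apart from masking. GAGAGA was in the windows of ranks 1, 4 and 61, and not in those of ranks 46 and 71. The 5 peaks were soft-masked over 19.9% of their windows on average (95% t interval 7.76 to 32.0%, highest 34.3%). By the criterion written beforehand repeats would put this mean above 41.8%, the 75th percentile of other pooled peaks, and their absence at or below the mean of those peaks, 28.8%. The interval excludes the former value and includes the latter, and the mean was above the 14.8% of all IDR peaks, so a minor part of repeats is not excluded. The interval was added after the mean was seen. Extra copies would raise weak peaks, here the pooled peaks that overlap no IDR peak, over the whole region. The gene with 20000 bp of flank held 27 weak pooled peaks, more than 90.8% of 109 equal windows around other IDR peaks, whose median was 19. Their median signal value was 14.2, against 11.4 over all weak pooled peaks and a median of 11.6 over those windows, of which 1 was as high. The comparison of signal values was added after the first of these values was seen. It goes with extra copies, while 10 of the windows were at least as dense, short of the level set for the number of peaks. Extra copies and a region dense in true sites would both raise these values, so they cannot be told apart. The labels speak of an insertion that targets unc-62 and of a transgenic line, and do not say whether the native gene or an added copy carries the tag.

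The ribosomal protein peaks could come from signal at strongly expressed genes of any kind. Other broadly expressed families, taken by 11 name prefixes such as those of tubulins, proteasome subunits and chaperonins, had IDR peaks at 2 of 71 testable genes, cct-8 and tba-2, with an odds ratio of 4.14 (95% interval 0.483 to 15.99, Fisher's exact test, two-sided, p = 0.0901). The interval includes both 1 and the ribosomal odds ratio of 10.005, so this test leaves the explanation open. A wider set of prefixes gave 7 of 148 genes and an odds ratio of 7.49, but it was tried first and drawn up with the names of IDR genes in view, including prefixes of genes already known to carry a peak, so it is not evidence. No biological explanation was tested.

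TGACA, the first 5 bases of the Meis core, was picked out from the scan of 6-base sequences in these same windows, so its values describe that choice and do not test it. TGACA was in 52 of 114 IDR windows, or 45.6%, against 33.0% of matched windows (odds ratio 1.70, 95% interval 1.13 to 2.56), and in Fisher's exact test of all 512 sequences of 5 bases its adjusted p was 0.0822. In the scan, TGACAC ranked 11 of 2080 (odds ratio 2.99, exact test, adjusted p = 0.00408). Whether simple GA and CA repeats account for it is left open. The matched windows were also not matched on coding sequence, whose part was not tested. Among the 45 IDR windows with neither GAGAGA nor ACACAC the odds ratio was 2.01 (95% interval 1.05 to 3.85), which meets the criterion written beforehand, but that criterion made no allowance for the choice of TGACA from the same windows, and over all 512 sequences the adjusted p of the exact test was 0.306. This allowance was added after the values were seen. Against windows 1000 bp to either side of the same summits the odds ratio of TGACA was 1.61, with an interval that includes 1 (0.992 to 2.62) and an exact p of 0.045, which makes no allowance for the choice of TGACA. Those windows were not matched on GC content or promoter status. A Meis-type site under the summit therefore remains a candidate explanation that these 114 peaks do not settle.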
